A study of Homo sapiens with 16 samples.

How the data were processed

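RNA was measured in 16 subcutaneous tumours grown in mice from HCT116, an established human colon cancer cell line. Per the labels, 8 tumours came from animals given distilled water and 8 from animals fed 500 mg/kg of Astragalus membranaceus, a root used in traditional Chinese medicine, each day for 28 days. The labels number the tumours 1 to 8 within each group and do not state that each tumour came from its own animal, so p-values measure the spread between these samples. Per the labels' protocols, total RNA was extracted with a column kit, then copied and biotin-labelled with the Affymetrix WT PLUS reagents, which also prime transcripts without a poly-A tail.

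The deposited values are log2 levels, 1 per probe set and array. Per the submitters' processing notes they were made with Affymetrix Expression Console and RMA, which corrects background, equalises the distributions of the arrays and summarises the probes of a probe set; versions and settings are not given in the sources used here. Per the series' design text, genes were then selected in GeneSpring at p below 0.05 and a fold change above 1.5, and neither the test nor any adjustment is named. Equalising the arrays means that a global difference in RNA amount cannot be read from these values. Array-wide differences remained in the deposited probe-set values, with medians from 5.21 to 5.56 and SDs from 1.86 to 2.08. Probes for short RNAs with many near-identical copies read several genes at once. An array has no read depth, so the number of arrays limits the precision. Human probes can also take up RNA of the mouse host.

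The table held 70523 probe sets. The probe annotation used here listed 25324 of them, 23781 with exactly 1 symbol and 1543 with several; the other 45199 are unnamed here. Of those with 1 symbol, 21497 were named through their gene identifier in the RefSeq gene table of assembly GRCh38.p14, 1974 by a current symbol, and 310 kept the annotation's symbol. A gene was represented by its probe set with the highest mean over the 16 arrays (479 of 22465 genes had more than 1). A gene was tested if its level exceeded the 40th percentile of all probe sets of that array on at least 8 arrays, which left 17312 genes. No coordinates are given, since the build behind the table is not stated.

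Treated and control tumours were compared with limma 3.58.1 in R 4.3.3 (linear model with empirical Bayes moderation, no block), with a 2-sided p adjusted by the Benjamini-Hochberg method and a threshold of 0.05. The submitters' thresholds were applied to the same fit, without adjustment. The share of the total sum of squares lying between the groups, the mean level of each gene list and the measures of the arrays were tested by exact 2-sided permutation over all 12870 assignments of the arrays to groups of 8; the smallest p these allow is 0.000155. Intervals are 95% intervals, from limma for genes and from inverting the exact test for lists. Lists with at least 5 tested members were tested (33 of 35), and adjusted over those 33; the erythroid list had 3 tested members and the mitochondrially encoded list 0. limma's camera and fry gave alternative list tests. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used for the rest.

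The gene lists, the tests, most of the alternative settings and the rule for named genes were fixed before the data were examined. The rule took, in each direction, genes past the adjusted threshold, filled to 10 with genes past the submitters' thresholds and then with the smallest p; the members of each list with the smallest p; members with the highest mean for the host, erythroid and housekeeping lists; and the 10 genes that varied most within groups. Genes outside this rule are said to have been chosen after their values were seen. Classes of short RNA and gene families, 18 in all, were also formed after the values were seen.

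The procedures were tested on simulated data. With known changes planted in 200 genes on the real residuals of this 8 against 8 comparison (17312 genes), limma recovered 45.4% of genes changed 1.25-fold, 86.2% at 1.5-fold, 98.0% at 2-fold and 100% at 3-fold. All fold sizes were planted together in each draw, which gave 1655 calls over 10 draws and eases the adjustment. A single changed gene faces a stricter cut-off and was not simulated. In the list test run over the 33 lists on shuffled residuals, 82.4% of lists shifted 1.25-fold and 97.4% of those shifted 1.5-fold were recovered, with a mean of 2.43% and 1.98% of calls false. Each draw shifted 8 of the 33 lists upward together, which also eases the adjustment. Only calls in the higher direction were counted, so false calls in the lower direction are left out of these percentages. A single shifted list was not simulated.

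Alternative settings fixed at that point changed the filter, the choice of probe set, the scaling, the moderation, the weighting of arrays, the block and the covariates, or left out each array in turn. Alternatives chosen after seeing the data used the poly-A spikes or the SD of each array as a covariate or counted genes with identical values once (17296 distinct). Others left out the U5 and U6 copies, or 3 arrays that stood apart: control replicates 6 and 8 and astragalus replicate 5. On these, 72, 54 and 57 genes lay more than 0.5 beyond every other array. Y-linked genes and XIST are not reported.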

Results

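Genome-wide RNA levels were compared between 8 tumours of mice fed Astragalus membranaceus and 8 tumours of mice given water, to ask which transcripts of HCT116 xenografts differ after 28 days of treatment. The 16 arrays were alike in overall level: the median log2 level over all probe sets was 5.36 ± 0.11 (SD, n = 8) in control and 5.38 ± 0.10 (SD, n = 8) in treated tumours. Pearson correlations across genes ranged from 0.940 to 0.994 between arrays of a group and from 0.940 to 0.993 between arrays of different groups. No pair of arrays held identical values.

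No gene differed between treated and control tumours past the adjusted threshold in limma, with 17312 genes tested. The smallest adjusted p was 0.680, for HLA-DRA, which encodes the alpha chain of the HLA-DR class II molecule. Its log2 level was 6.23 ± 0.19 (SD, n = 8) in control and 6.83 ± 0.28 (SD, n = 8) in treated tumours, a difference of 0.60 (95% interval 0.37 to 0.83; limma unadjusted p = 3.93e-05, adjusted p = 0.680). At an unadjusted limma p below 0.05 there were 443 genes, 282 higher and 161 lower in treated tumours, against 865.6 expected by chance. That balance depended on scaling and on single arrays: 281 were higher and 339 lower after quantile normalisation, 219 and 228 with equal array medians, 1085 and 1176 with array weights, and 507 and 822 without astragalus replicate 2. The unmoderated test on the same values also gave 0 genes past the adjusted threshold, while 40 genes were higher with the SD of each array as a covariate, chosen after seeing the data, and 1 without astragalus replicate 2; the spike covariate is given with the control transcripts. The 95% interval of the difference lay within 1.5-fold either way for 16917 genes (97.7%) and within 2-fold for 17267 (99.7%), with a median width of 0.17 on either side.

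The submitters' thresholds, a fold above 1.5 with an unadjusted p below 0.05, were met by 41 genes, all higher in treated tumours. Of these, 31 were copies of U6 and 7 of U5, small nuclear RNAs of the spliceosome that splices pre-mRNA. The remaining 3 were HLA-DRA, the small nucleolar RNA gene SNORA53 (difference 0.59) and the 5S ribosomal RNA pseudogene RNA5SP348 (difference 0.74), the last pair chosen after their values were seen. The U6 copies with the smallest p included RNU6-16P (10.47 ± 0.32 in control, 11.11 ± 0.35 in treated tumours), RNU6-15P (10.74 ± 0.32 and 11.37 ± 0.36), RNU6-36P (10.71 ± 0.36 and 11.36 ± 0.36), RNU6-33P (10.56 ± 0.35 and 11.20 ± 0.36) and RNU6-27 (7.88 ± 0.46 and 8.66 ± 0.44), each mean ± SD with n = 8, and RNU6-14P differed by 0.78. RNU6-1, RNU6-11 and RNU6-37 carried identical values on every array (10.75 ± 0.35 and 11.38 ± 0.35), so these copies are not separate measurements. All 9 had a limma adjusted p of 0.996. The number higher by the thresholds fell to 20 without control replicate 8, to 20 without astragalus replicate 1 and to 25 without astragalus replicate 5, and was 24 with the host marker mean as a covariate. Other settings raised it and gave genes in the lower direction: 163 higher and 25 lower over every transcript cluster, and 45 and 9 with array weights. With the spike mean as a covariate, chosen after seeing the data, 272 were higher and 255 lower.

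**Figure D1:**
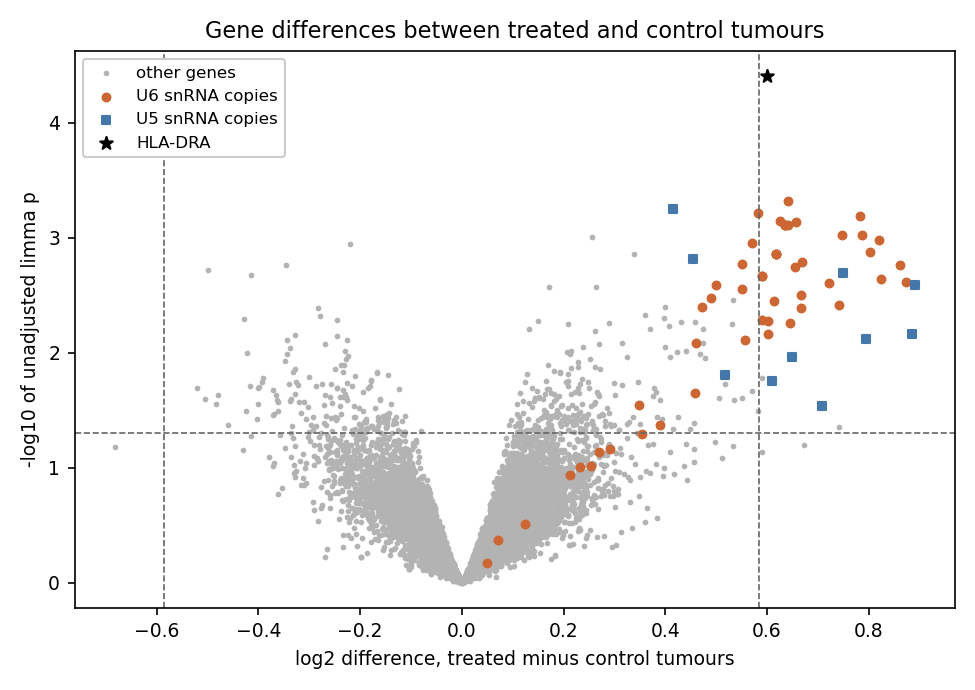
Log2 difference (treated minus control, horizontal axis) against the -log10 of the unadjusted limma p (vertical axis), 1 point per tested gene, with U6 copies, U5 copies and HLA-DRA marked. Dashed lines mark the submitters' thresholds, and all 41 genes beyond both lie on the right.

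Averaged over copies, in classes formed after the values were seen, U6 was 8.23 ± 0.33 in control and 8.77 ± 0.37 in treated tumours (SD, n = 8 each; exact permutation p = 0.0087, adjusted p = 0.0392 over 18 classes), and all 53 tested U6 copies had a difference above 0. U5 was 7.64 ± 0.58 and 8.31 ± 0.28 (SD, n = 8 each; exact permutation p = 0.00451, adjusted p = 0.0373), with all 10 copies above 0. Both classes were formed because their copies met the submitters' thresholds, so these p-values are not independent evidence. On the same arrays the spikes added before labelling were lower by a log2 difference of -0.45 in treated tumours, as given with the control transcripts.

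**Figure D2:**
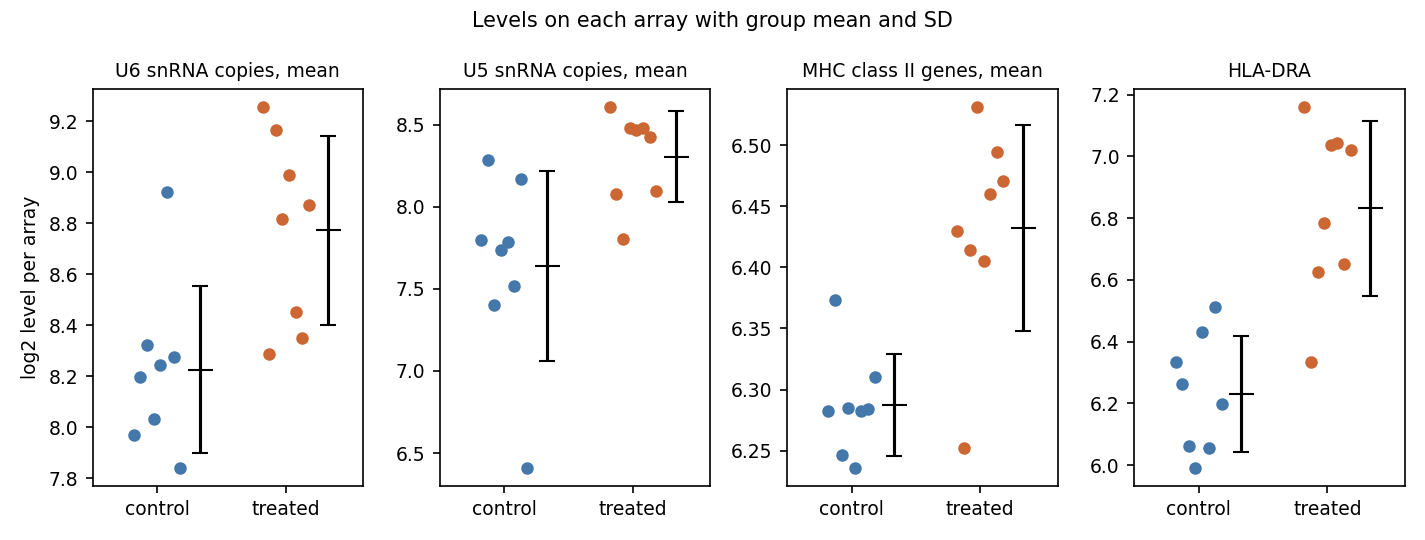
Log2 level on each array (vertical axes) of the mean of the U6 copies, the U5 copies and the MHC class II genes, and of HLA-DRA, for control and treated tumours, with group mean and SD to the right of the points. HLA-DRA ran from 5.99 to 6.51 in control and from 6.33 to 7.16 in treated tumours, so the groups overlap.

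No gene met those thresholds in the lower direction. The genes with the smallest p there were CFAP53, a protein of motile cilia (difference -0.22), FMNL2, a formin that acts on actin filaments (-0.35), ENO1-IT1 (-0.50), PITPNC1, a phosphatidylinositol transfer protein (-0.42), MGC32805 (-0.28), ANKRD20A5P (-0.28), POTEE (-0.43), LINC00342 (-0.33), IL1RAPL1 (-0.24) and a transcript with a clone-based name (-0.25), all with a limma adjusted p of 0.996.

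The profile as a whole did not separate by treatment. The groups accounted for 6.76% of the total sum of squares over the tested genes (exact permutation p = 0.378), where the median over all assignments of the arrays was 5.67%. The first components carried 39.2% and 25.7% of the variance, with mean scores that differed between groups by 0.80 (exact p = 0.927) and 10.4 (exact p = 0.130). The highest score on the first component, 33.8, was that of control replicate 6, the array with the smallest SD (1.86). The lowest, -18.9, was that of astragalus replicate 2, with the largest SD (2.08). The first component may thus partly reflect the range of values on the arrays, which was not tested.

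The genes that varied most between tumours, whatever their group, included CXCL8, a neutrophil-attracting chemokine, whose level ran from 4.88 to 8.80, and the interferon-induced gene IFI44L, from 4.96 to 8.06. The others were LINC00273 (9.35 to 13.01), REXO1L1P (6.36 to 9.16), USP17L6P (5.63 to 8.21), LINC00415 (7.09 to 9.21), MIR663A (8.18 to 10.98) and the 5S ribosomal pseudogenes RNA5SP312, RNA5SP313 and RNA5SP315, which shared identical values from 4.41 to 7.31.

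None of the 33 gene lists shifted past the adjusted threshold by exact permutation of array means (smallest adjusted p = 0.880). All 33 intervals lay within 1.5-fold either way. The preset-correlation form of camera called 9 lists, 4 higher (small nucleolar RNAs, oxidative phosphorylation, proteasome, ribosomal proteins) and 5 lower (MAPK and immediate early genes, interferon response, glycolysis, epithelial junctions, hypoxia). No call held (smallest adjusted p = 0.912 with an estimated correlation), and fry called 0 lists.

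**Figure D3:**
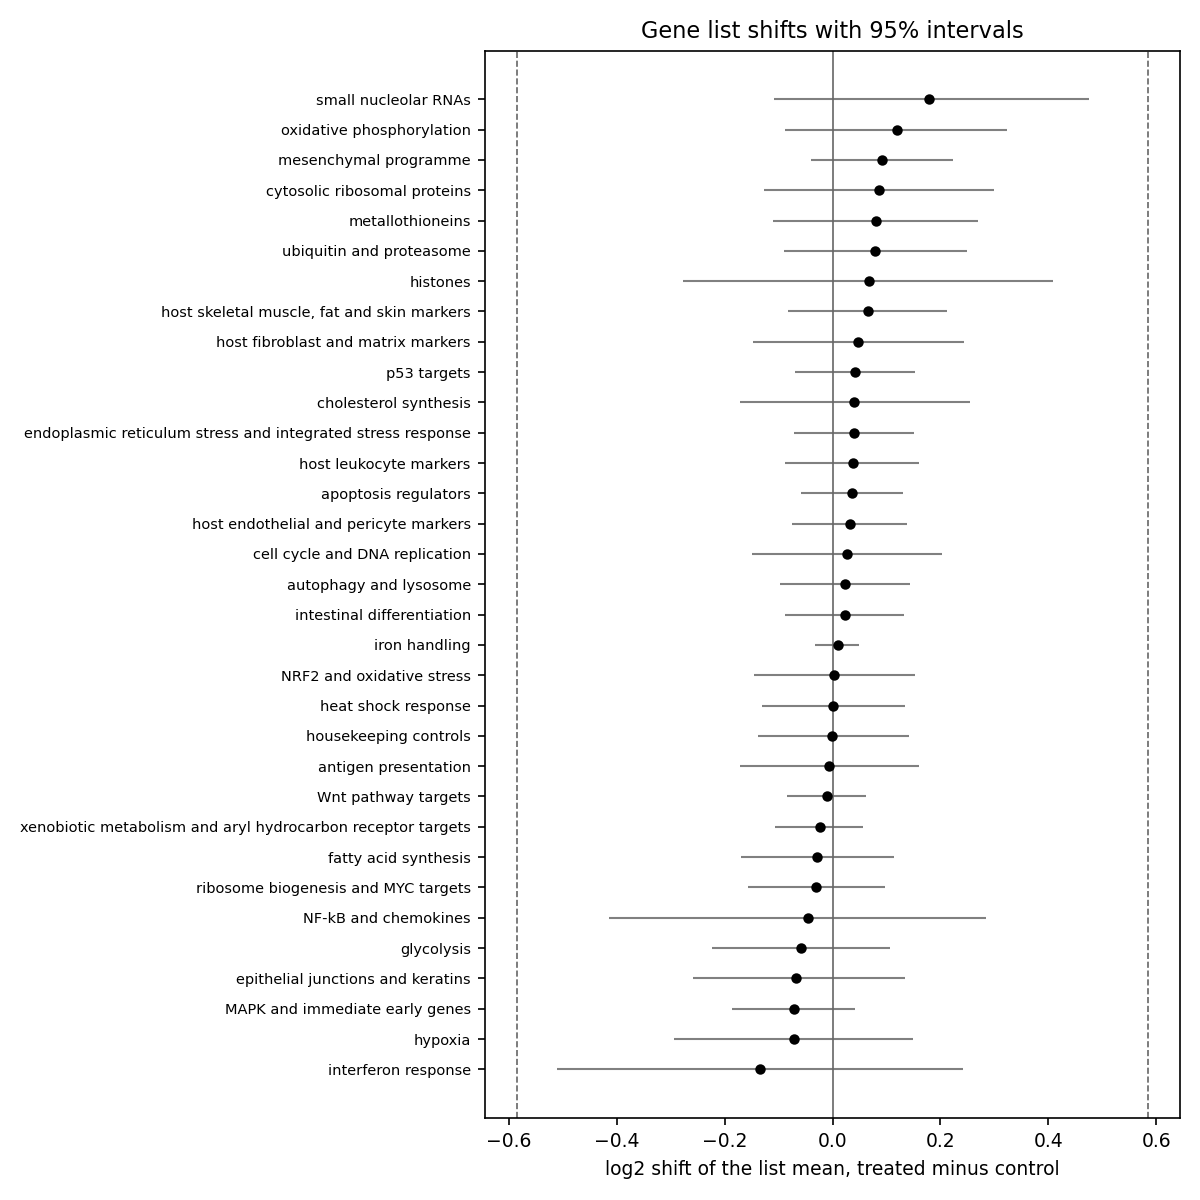
Log2 shift of each list's mean level (treated minus control, horizontal axis) with its 95% interval, 1 line per gene list. Dashed lines mark 1.5-fold; every interval includes 0, and the widest shift is 0.18 for the small nucleolar RNAs.

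Lists of growth and survival genes stayed near 0. Cell cycle and DNA replication genes shifted by 0.03 (interval -0.15 to 0.20), with CCNB2, a mitotic cyclin, differing by 0.25 and MCM7, of the replicative helicase, by -0.19. Histones shifted by 0.07 (-0.28 to 0.41; H2BC14 0.27, H2AC6 0.10), p53 targets by 0.04 (-0.07 to 0.15; TIGAR 0.17, GADD45A -0.17), and ribosome biogenesis and MYC targets by -0.03 (-0.16 to 0.10; NOP16 0.15, NCL -0.22). Apoptosis regulators shifted by 0.04 (-0.06 to 0.13). In that list 1 of 18 members, BIK, a BH3-only protein that promotes apoptosis, was higher in treated tumours when adjusted over the list alone (8.17 ± 0.13 against 8.42 ± 0.11, SD, n = 8), and 0 were when adjusted over all genes (limma adjusted p = 0.996); BAK1 differed by 0.11. In the other 32 lists 0 members passed when adjusted over the list alone.

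Metabolic and stress lists also gave intervals that included 0. The shifts were -0.07 for hypoxia (BHLHE40 -0.30, SLC2A1 -0.22), -0.06 for glycolysis (PFKM -0.12, PGAM1 0.14), 0.12 for oxidative phosphorylation (ATP5PO 0.27, COX7B 0.32) and 0.09 for cytosolic ribosomal proteins (RPL24 0.21, RPS6 0.17). Endoplasmic reticulum stress genes shifted by 0.04, with XBP1, a transcription factor of the unfolded protein response, differing by 0.17 and DNAJB9 by 0.14. The shift was 0.00 for NRF2 targets (TXN 0.26, SLC7A11 -0.26), while heat shock genes moved by less than 0.01 (HSPA1A -0.13, HSPE1 0.10). Metallothioneins shifted by 0.08 (MT1X 0.20, MT1G 0.07), autophagy and lysosome genes by 0.02 (GABARAPL1 -0.18, WIPI1 0.13), and ubiquitin and proteasome genes by 0.08 (PSMB6 0.20, PSMA2 0.20). Cholesterol synthesis shifted by 0.04 (EBP 0.18, FDPS 0.11), fatty acid synthesis by -0.03 (GPAM 0.14, ACACA -0.23), iron handling by 0.01 (ACO1 0.08, STEAP3 -0.05) and xenobiotic metabolism by -0.02 (ABCC2 -0.35, CYP1A1 0.08).

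Lists of tumour cell identity and signalling showed no shift past the threshold. Wnt targets shifted by -0.01 (CD44 -0.17, CCND1 -0.13), intestinal differentiation by 0.02 (TFF1 0.16, ALPI 0.08) and epithelial junctions and keratins by -0.07 (JUP -0.22, TJP1 -0.18). The mesenchymal list shifted by 0.09 (-0.04 to 0.22), with MMP7, a matrix metalloproteinase, differing by 0.55 and TGFBI by 0.17. MAPK and immediate early genes shifted by -0.07, with EGR1 at -0.42 and DUSP5 at -0.26. The interferon list shifted by -0.13 (-0.51 to 0.24), with OAS3 at -0.34 and IFI44L at -0.68, class I antigen presentation by -0.01 (TAP2 -0.12, TAPBP -0.11), and NF-kB and chemokines by -0.04 (TNF -0.10, NFKB1 -0.11). Small nucleolar RNAs, which guide modification of ribosomal RNA, shifted by 0.18 (-0.11 to 0.48), with all 15 members above 0 (SNORA14B 0.38, SNORD14E 0.42).

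Lists of mouse host tissue showed no shift past the threshold. The fibroblast and matrix list shifted by 0.05 (COL6A1 -0.05, COL6A2 -0.03, FN1 0.22, TAGLN 0.07), the endothelial and pericyte list by 0.03 (CDH5 0.10, CSPG4 0.06, EGFL7 0.03, MCAM 0.02), the leukocyte list by 0.04 (CD74 0.11, FCER1G 0.11, CD68 -0.06, TYROBP -0.02), and the list of muscle, fat and skin markers by 0.06 (KRT10 0.16, KRT5 0.41, ACTA1 -0.03). The mean shift of the fibroblast, endothelial and leukocyte lists was 0.04. Of the erythroid list, too small to test, SLC4A1 differed by 0.06 and EPB42 by 0.02. Housekeeping genes shifted by less than 0.01, with TBP at 0.15, POLR2A at -0.19, GAPDH at -0.05 and B2M at 0.05.

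Transcripts added before labelling differed between the groups. The mean of the 4 poly-A spikes was 9.06 ± 0.17 (SD, n = 8) in control and 8.61 ± 0.21 (SD, n = 8) in treated arrays, a difference of -0.45 (exact permutation p = 0.000466, adjusted p = 0.0021 over 18 array measures). The spikes phe, thr and dap differed by -0.54, -0.53 and -0.42 (exact permutation, adjusted p = 0.0021 each). The lys spike differed by -0.30 and did not pass after adjustment (exact permutation p = 0.0378, adjusted p = 0.136). The hybridisation controls, added after labelling, differed by 0.03 (exact p = 0.818), and the SD of the arrays by less than 0.01 (exact p = 0.885). With the spike mean as a covariate, chosen after seeing the data, limma gave 5 genes higher and 52 lower past the adjusted threshold.

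**Figure D4:**
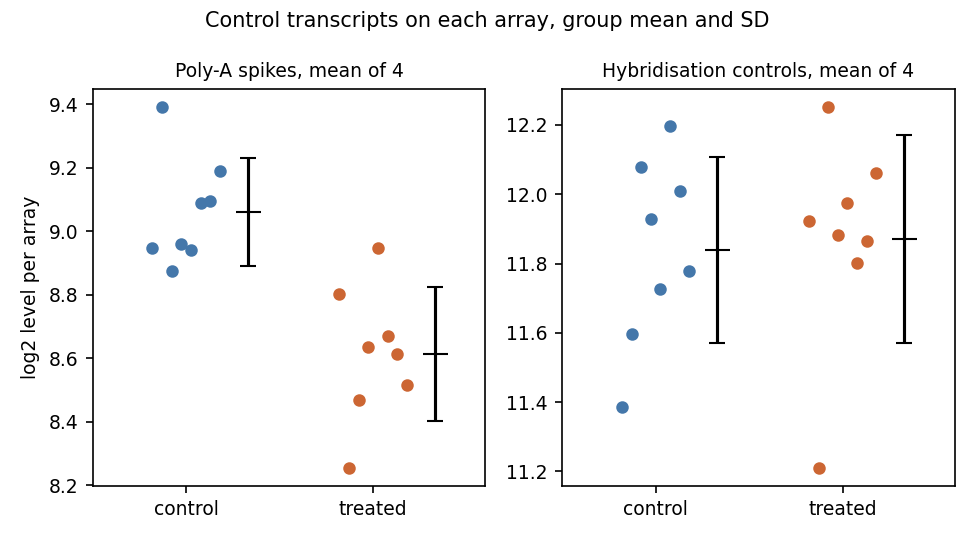
Mean log2 level of 4 poly-A spikes (left) and 4 hybridisation controls (right) on each array, with group mean and SD to the right of the points. Spike means ran from 8.87 to 9.39 in control and from 8.26 to 8.95 in treated arrays.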

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

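The tests of short RNA recovery, of the range of the arrays, of host leukocytes and class I antigen presentation, of the range of control replicate 8 and all counts over splits were chosen after the result was seen. Only the tests of the spikes against U6, of host tissue and of differentiation were set before.

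The U6 copies were higher in treated tumours by 0.55, and the shift stayed between 0.48 and 0.65 when each array was left out in turn. The range of values differed little between the groups (SD difference 0.0045, exact permutation p = 0.885), which argues against a group difference in range. With the SD of each array as a covariate the shift was 0.57 (permutation p = 0.000155, the smallest possible). A covariate so balanced between the groups could hardly lower the shift, so that fit decides nothing more. A general gain of short RNAs stays open: the gap between U6 and 7 other short classes was larger by 0.35 in treated tumours (exact permutation p = 0.0639), while those classes shifted by 0.19 (exact p = 0.110). The difference seen in the poly-A spikes, whose source was not tested, may also contribute and cannot be told apart from treatment. Spikes and U6 were too loosely related within groups to decide (r = 0.26, permutation p = 0.357, Spearman rho = 0.19, permutation p = 0.515). Without the 2 farthest arrays r was -0.0044. An effect of Astragalus also stays open.

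HLA-DRA was higher in treated tumours by 0.60, between 0.55 and 0.67 when each array was left out, and its limma adjusted p was 0.048 without astragalus replicate 2 against 0.680 with all arrays. A response that raises class I antigen presentation genes by 0.30, set as the least it should show, is argued against. The upper bound of the shift of that list, which holds no class II gene, was 0.16. A smaller rise of class I genes stays open, because the class II genes without HLA-DRA also lay below 0.30 (shift 0.12, upper bound 0.18). A response of class II genes, the class of HLA-DRA, stays open too. Host leukocytes may still be a source. The upper bound of the leukocyte list was also 0.16, but the list's median gene lay at the 31.9th percentile of level. That is too dim on human probes for this to decide, a condition added after the values were seen. HLA-DRA was itself at a low level, 6.23 in control and 6.83 in treated tumours, where the leukocyte list averaged 6.12 and 6.16. Within groups the leukocyte list and HLA-DRA were related by r = -0.11 (permutation p = 0.679; Spearman rho = -0.19, permutation p = 0.502; r = -0.42 without the 2 farthest arrays). For this gene neither a direct effect of treatment nor the difference seen in the spikes was tested.

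Control replicate 8 scored -22.0 on the third component, where the other controls ran from -1.54 to 5.93. An unusual range of values is argued against, as its SD of 2.01 lay within the 1.86 to 2.08 of the other 15 arrays. More or less host tissue stays open: 3 of 3 host lists lay inside the range of the others, but their median genes lay at the 31.9th to 42.7th percentile of level, too dim on human probes to decide, a condition added after the values were seen. Another differentiation state of the tumour cells may be involved but also stays open, since 1 of 2 lists lay outside: epithelial junctions at 9.26 (others 8.60 to 9.23), and not intestinal differentiation at 5.96 (5.76 to 6.08).

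In 23 of 344 groups of 8 values, 1 array lay far from the other 7, where chance gives about 1 in 20. Control replicate 8 was highest for ANKRD20A5P (5.92) and lowest for BAK1 (6.45), EGFL7 (7.47), U2 (6.54) and U5 (6.41). Control replicate 6 was highest for CXCL8 (8.80), TNF (6.23), NFKB1 (7.81), the NF-kB and chemokine list (7.71), U1 (9.46), U6 (8.93) and 5S ribosomal RNA copies (7.02). Astragalus replicate 2 was lowest for the hybridisation controls bioB (8.85), bioC (10.35) and bioD (12.12), for their mean with cre (11.21) and for the MHC class II genes (6.25), and highest for COL6A1 (8.57). COL6A1 was also far higher in control replicate 5 (8.60) than in the other controls. The remaining values were IL1RAPL1 in astragalus replicate 6 (5.47), TGFBI in astragalus replicate 1 (6.17) and the iron handling list in astragalus replicate 3 (7.50).

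For the number of genes past the submitters' thresholds, 3 of 100 splits of the arrays, the real one included, gave as many as the real 41 (highest other 49). Only 100 of the 6435 possible splits were drawn, and this count was chosen after the result was seen, so chance was not excluded. The low share also rests on single arrays. Without control replicate 8 the number fell to 20, and 7 of 50 splits of the other 15 arrays gave as many (highest other 69). Without astragalus replicate 1 it fell to 20, and 9 of 50 did (highest other 95), so chance was not excluded there either. Outside U5 and U6, 50 of 100 splits gave as many as the real 3 (highest other 44), so chance was not excluded there. For genes past the adjusted threshold (100 of 100 splits, highest other 0) and gene lists (6435 of 6435, highest other 23) the real number is 0, which every split reaches by construction, so these counts say nothing about chance. At an unadjusted p below 0.05 the real 443 genes lay near the median of 430 over the other splits, and 47 of 100 gave at least as many. The highest, 6594 genes, points to a structure among the arrays that does not follow treatment.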

How the results depend on the processing

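The alternatives with the poly-A spike mean, the SD of each array, identical values counted once, U5 and U6 copies left out and 3 arrays left out were chosen after seeing the data. The absence of genes past the adjusted threshold held with all 16 arrays under each alternative set before the data were examined, and with identical values counted once, U5 and U6 copies left out or the 3 arrays left out; leaving out 1 array gave 0 to 1 genes higher, the 1 being HLA-DRA without astragalus replicate 2. With the SD of each array as a covariate 40 genes were higher, and with the spike mean 5 were higher and 52 lower, where spike level and group are hard to part; the cause was not tested. The labels do not say whether equal replicate numbers share anything. With group means removed, profiles of same-numbered samples correlated between -0.63 and 0.68, and 1 of 8 controls correlated best with its own number. No general pairing was seen in these values, which cannot exclude one in the design. With replicate as a block 0 genes passed the adjusted threshold, 43 genes were higher and 1 lower by the submitters' thresholds, and the groups accounted for 12.1% (exact p = 0.438); it changed no other call.

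Genes higher by the submitters' thresholds, 41 with all arrays, numbered 163 over every transcript cluster (40196 tested), 24 with the host marker mean as a covariate, 272 with the spike mean, 3 without U5 and U6 copies, and 20 to 48 when 1 array was left out. Genes lower, 0 with all arrays, numbered 25 over every transcript cluster, 9 with array weights, 255 with the spike mean, 0 to 3 with 1 array left out, and 1 without the filter, after quantile normalisation, with the block, with the cell cycle mean, with the SD of each array or without the 3 arrays. Camera with a preset correlation called 4 lists higher and 5 lower. Lists at an unadjusted exact p below 0.05 numbered 0 in the reported test, 3 (lower) with the spike mean and 1 each with medians of members, the host mean, the block, the SD of each array, without control replicate 2 and without control replicate 6; none passed after adjustment. Except where construction shows it, the cause was not tested.

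Of 97 named genes and 33 lists, 1050 of 1055 and 305 of 326 values under the alternatives set beforehand kept direction and side of the threshold. Under those chosen after seeing the data 455 of 474 and 83 of 99 did, and 12 values of named genes came to pass the adjusted threshold. With 1 array left out 1547 of 1552 and 483 of 528 did. None of the values that turned direction came from a result past its threshold, and the cause was not tested. With the spike mean as a covariate they were -0.00220 for cell cycle, -0.0197 for the mesenchymal list, 0.0687 for antigen presentation, -0.0516 for host fibroblasts, 0.0142 for xenobiotic metabolism, -0.10 for CSPG4, -0.11 for MCAM and -0.0924 for ACO1. Without the 3 arrays they were -0.0295 for cell cycle, -0.11 for histones, -0.0109 for ribosomal proteins, 0.0124 for heat shock, -0.0356 for NRF2, -0.00960 for autophagy, -0.0100 for cholesterol synthesis, 0.00386 for Wnt, 0.13 for NF-kB, -0.00242 for iron handling, -0.0469 for H2AC6, 0.0191 for NFKB1, -0.00285 for MCAM and -0.00869 for B2M. Medians of members gave -0.0138 for p53 targets, 0.0752 for heat shock, 0.0237 for Wnt, -0.0124 for intestinal differentiation, -0.00457 for host endothelium and 0.0460 for xenobiotic metabolism. The stricter filter gave 0.00223 for heat shock and -0.000649 for NRF2. The mean of all probe sets of a gene gave 0.00290 for heat shock. The host mean as a covariate gave 0.0280 for heat shock, -0.00394 for intestinal differentiation, 0.0323 for antigen presentation, 0.0375 for housekeeping genes and -0.0151 for EPB42. Quantile normalisation gave -0.0280 for NRF2, -0.00507 for intestinal differentiation, -0.0104 for iron handling, -0.00410 for EPB42 and -0.0194 for B2M. Equal array medians gave -0.0142 for NRF2 and -0.00741 for iron handling. The cell cycle mean as a covariate gave -0.0151 for NRF2. The SD of each array gave -0.00536 for NRF2. Scaling members to an SD of 1 gave 0.0138 for Wnt and 0.0406 for xenobiotic metabolism. Array weights gave -0.0308 for MCAM and 0.00127 for TYROBP.

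With 1 array left out, ranges that crossed 0 were -0.0169 to 0.0676 for cell cycle, -0.000310 to 0.14 for histones, -0.0394 to 0.0187 for heat shock, -0.0304 to 0.0348 for NRF2, -0.00575 to 0.0454 for autophagy, -0.0172 to 0.0832 for cholesterol synthesis, -0.0618 to 0.00567 for fatty acid synthesis, -0.0215 to 0.00826 for Wnt, -0.0341 to 0.0279 for antigen presentation, -0.11 to 0.0940 for NF-kB, -0.0463 to 0.000617 for xenobiotic metabolism, -0.0378 to 0.0239 for housekeeping genes, -0.0132 to 0.0536 for MCAM and -0.0310 to 0.14 for B2M. The median genes of the host fibroblast, endothelial and leukocyte lists are in the dimmer part of the tested genes, which limits what these lists can show.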

Other observations

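Gene classes in this part, like the genes named in it, were chosen after their values were seen. The MHC class II genes, taken as 15 HLA-D genes with CD74 and their activator CIITA, were grouped because HLA-DRA ranked first. As a class they were higher in treated tumours: 6.29 ± 0.04 against 6.43 ± 0.08 (SD, n = 8 each), a shift of 0.14 (exact permutation p = 0.00186, adjusted p = 0.0336 over 18 classes), with all 17 tested genes above 0. Because the class includes the gene that prompted it, this p is not independent evidence. Without HLA-DRA the shift was 0.12 (exact p = 0.00528); the other 4 HLA-DR genes shifted by 0.24 (exact p = 0.00606) and the 12 genes outside HLA-DR by 0.08 (exact p = 0.0421), each p unadjusted and the 2 shifts not tested against each other. HLA-DRB4 differed by 0.34, HLA-DRB1 by 0.27, HLA-DRB5 by 0.17, HLA-DPA1 by 0.08 and CIITA by 0.06. The 12 genes outside HLA-DR were dim: they averaged 5.90 in control and 5.98 in treated tumours. The median over all probe sets was 5.36 and 5.38. Whether the HLA-DR probe sets measure separate transcripts was not tested. On the same arrays the poly-A spikes differed by -0.45, and the treated array lowest for the class, astragalus replicate 2 (6.25), was also lowest for the hybridisation controls. No class II gene passed the limma adjusted threshold over all genes. The 8 POTE family genes, only some of which share sequence with actin, had a shift of -0.28, all below 0 (exact permutation p = 0.0211, adjusted p = 0.0603). ACTB differed by -0.07.

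Other short RNAs shifted by different amounts, which were not tested against each other. U2 shifted by 0.39 (exact p = 0.0196, adjusted p = 0.0603), U4 by 0.31 (exact p = 0.0235, adjusted p = 0.0603), U1 by 0.07 (exact p = 0.712) and U7 by -0.23 (exact p = 0.0747). Control replicate 6 was far above the other controls for U1 (9.46, others 8.27 to 8.56) and for 5S copies (7.02, others 6.12 to 6.52). This lowers both shifts. The 7SL RNA of the signal recognition particle was higher in treated tumours by 0.09 (exact p = 0.00622, adjusted p = 0.0373). It was read by 1 probe set, at 13.95 in control and 14.04 in treated tumours, and its unadjusted limma p was not below 0.05. Shifts were 0.15 for C/D and 0.17 for H/ACA small nucleolar RNAs, 0.20 for scaRNAs, 0.10 for 5S ribosomal RNA copies, 0.08 for 7SK, 0.06 for Y RNAs, 0.02 for microRNA genes, 0.21 for the USP17L family and 0.02 for LINC genes, each with an exact p above 0.2. In control replicate 8, GALNT5 (7.62), MACC1 (8.56), OAS2 (6.41), XAF1 (8.93) and EHF (8.61) lay above every other array, with the highest interferon list (8.22) and hypoxia list (8.65).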
